A study of Homo sapiens with 3 samples.

How the data were processed

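The series holds 3 libraries from 786-O cells, a human clear cell renal carcinoma line: chromatin immunoprecipitated for the acetylated histone H3K27ac, chromatin immunoprecipitated for the transcription factor TEAD, and input chromatin. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min, chromatin was sonicated, and amplified libraries were selected for lengths of 300 to 700 bp. The peak identifiers inside the TEAD list carry the names TEF1 and TEF3; which TEAD protein the antibody recognises was taken no further than the label. Each group had 1 library, so no difference below has a replicate check. Every p-value compares positions or regions within these libraries and says nothing about the spread between cultures.

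The values used were the peak lists that the authors deposited, 1 for H3K27ac and 1 for TEAD, each called on a single library. No peak list, read count or signal track of the input library was used here. Per the submitters' processing notes, the tools were fastp, Bowtie2 2.4.5 and MACS2, and the genome build was hg19. The notes give no role, order or parameters for them. The significance threshold and any removal of peaks are not given in the sources used here. The lowest deposited −log10 q was 2.05 for H3K27ac and 2.03 for TEAD, and the peak numbers skipped 28 values in the H3K27ac list and 133 in the TEAD list. For each peak the authors deposited the fold enrichment at the summit over the caller's local background, the −log10 p and −log10 q of the summit, and the distance of the summit from the peak start. A whole-number score was deposited by the authors as well; it lay within 1 unit of 10 times the −log10 q for all peaks and was not used. All of these are the authors' own values for each peak and were used to rank, filter or describe peaks within a list.

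Peaks on chromosomes 1 to 22 and X were kept, 52667 for H3K27ac and 35241 for TEAD. The 183 H3K27ac and 123 TEAD peaks on chromosome Y were left out, as fixed beforehand. No interval was listed more than once. A kept peak is called a region below, and coordinates are hg19 positions counted from 1. A TEAD region that shared at least 1 bp with an H3K27ac region is called marked.

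The local background and read pileup at each summit were recovered from the deposited fold and −log10 p. The pileup k and background b were taken as the pair with a whole-number k for which (k + 1)/(b + 1) equals the fold and the Poisson probability of more than k reads equals p. A whole-number k met both within 0.002 of the −log10 p for 100% of the regions in both lists. After the p-values of a list were shuffled among 5000 of its regions, 0.86% (H3K27ac) and 0.72% (TEAD) met the same tolerance. The recovered background had a floor of 1.45 reads for H3K27ac and 1.30 for TEAD and otherwise moved in steps that included 0.706 and 0.702 reads. Such steps arise from a control library scaled to the depth of the ChIP library. The series lists 1 input library, but which control was used is not given in the sources used here, so the value is called the recovered background.

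Recovered values give the depth. Each floor was divided by the shortest region of its list, 299 bp for H3K27ac and 269 bp for TEAD. These widths were assumed to be the fragment lengths. The ratio of TEAD to H3K27ac library size was 0.994 from these divided floors and 0.994 from the steps, so the libraries were of nearly equal depth. The absolute number of reads is not given in the sources used here. The summit pileup had a median of 24 reads in both lists and never fell below 7. Intervals on shares are 95% Wilson intervals and intervals on pileups are exact 95% Poisson intervals. Both cover counting error only, and the reads carry no molecular identifiers. An unmarked TEAD region is one where no H3K27ac peak passed the caller at this depth, not one shown to lack the mark.

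Overlap was compared with 1000 random placements of the TEAD regions on their own chromosomes with their own widths. Chromosome gaps were not annotated here, so 276 stretches longer than 1 Mb without a peak of either list took no placement, which left 2332 Mb. The placement p is two-sided and cannot fall below 0.002. Mean log2 fold was compared between classes of regions with a two-sided permutation test of 100000 resamples, whose smallest p is 1e-05. H3K27ac regions were joined into domains over gaps of up to 12.5 kb and ranked by the sum of fold times width. Domains above the point where the scaled rank curve reaches slope 1 are called large. Shares of H3K27ac regions with TEAD were compared between large and other domains by a Mantel-Haenszel ratio over width deciles, with 10000 permutations within deciles and a smallest two-sided p of 0.0002. These 3 tests, their thresholds of 0.05 and part of the alternatives were fixed before the data were examined. The stretches without a peak were not in the plan and replaced its exclusion of assembly gaps. The recovery of pileups, the share of H3K27ac regions with TEAD against placements, the summit distances, the TEAD summits per 10 kb of H3K27ac, the fold of H3K27ac regions with and without TEAD, the distance of unmarked TEAD regions from H3K27ac and the comparisons by decile, background or chromosome were added after the lists had been seen. Alternatives covered stricter peak thresholds (−log10 q or fold of at least 5), other definitions of overlap (summit inside, or 50% of the TEAD region covered), other placements and other stitching gaps.

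The statistics were tested on simulated data, apart from the summits per 10 kb, the stratified differences of marked shares and the ratios of mean background in the closing section. For the overlap of 35241 simulated TEAD regions, a planted overlap of 52.2% was found as 52.3%. In the same number of regions a planted difference of 0.2 in mean log2 fold was found as 0.21, and for 52667 simulated H3K27ac regions a planted stratified ratio of 1.5 was found as 1.51. Within width deciles of 52667 simulated H3K27ac regions a planted difference of 0.2 in mean log2 fold was found as 0.21. A planted summit depletion ratio of 0.766 was found as 0.771 in 17015 simulated summits, and a planted share of 28.5% near H3K27ac as 28.7% in 16210 simulated unmarked regions. A planted correlation of 0.7 was found as 0.69 over 4577 simulated pairs of adjacent bins. In 998 simulated peaks the right pileup was recovered for 100%. The simulated pileups and backgrounds did not span the whole observed range, and no simulated background reached 10 reads. Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

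The planned comparisons of promoter shares, sequence motifs (TEAD, NF-κB, AP-1 and others) and gene lists need the sequence or gene positions of hg19, which were not used here; the gene table at hand follows GRCh38, and coordinates were not converted. The rule fixed for named genes took the genes at the 10 marked TEAD summits of highest fold, at the 10 highest-ranked domains and at members of the fixed lists. Of these only the first 2 parts applied, and they name regions in place of genes. The 10 unmarked TEAD regions of highest fold and the H3K27ac regions with the most TEAD regions were named after their values had been seen.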

Results

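The data comprise genome-wide peak lists for H3K27ac, a histone mark of active promoters and enhancers, and for TEAD, the DNA-binding partner of the Hippo pathway co-activator YAP, in 786-O clear cell renal carcinoma cells. The series' title places TEAD in a complex with NF-κB, and the design pairs the TEAD profile with the acetylation profile of the same line. H3K27ac had 52667 regions covering 75.9 Mb, with a median width of 950 bp (interquartile range 499 to 1852 bp). TEAD had 35241 regions covering 18.3 Mb, with a median width of 463 bp (356 to 609 bp). The median fold enrichment at the summit was 6.54 for H3K27ac and 7.14 for TEAD. The strongest TEAD region reached 145-fold and the strongest H3K27ac region 50.7-fold. Each profile rests on 1 library of nearly equal depth, with a median of 24 reads at the summit in both.

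The first comparison asked how much of TEAD occupancy lay in acetylated chromatin. Of the TEAD regions, 24109 overlapped an H3K27ac region, a share of 68.4% (95% interval 67.9 to 68.9%). Random placements of the TEAD regions reached 4.45% ± 0.11 (SD, 1000 placements), so the observed share was 15.4 times the placed one (permutation p = 0.002, the smallest possible). TEAD summits lay inside an H3K27ac region for 55.3% of regions. Against TEAD regions moved only 5 to 50 kb from their own position, which overlapped H3K27ac in 10.3%, the ratio was 6.62. Without a profile of another factor, these ratios do not show whether the excess is particular to TEAD. In the other direction 21966 H3K27ac regions, 41.7% (41.3 to 42.1%), carried at least 1 TEAD region, against 2.99% ± 0.07 (SD) in the placements. Most of these carried exactly 1 TEAD region (18872 regions), 2424 carried 2 and 670 carried 3 or more.

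TEAD enrichment was higher at marked than at unmarked TEAD regions, by a small margin. The median fold was 7.41 at the 24109 marked regions and 6.83 at the 11132 unmarked ones. Mean log2 fold was 3.10 ± 0.92 (SD) and 2.92 ± 0.70 (SD), a difference of 0.17 ± 0.01 (SE; permutation p = 1e-05, the smallest possible). The difference was 0.04 when a region counted as marked only if its summit lay inside H3K27ac, with median folds of 7.15 and 7.10. It was 0.27 within deciles of recovered background and 0.46 for the log2 summit pileup. Marked regions, as first defined, were also wider, with a median of 509 bp against 391 bp. A wider region can touch H3K27ac by size alone, and no comparison at equal width was run. The 4617 TEAD regions that overlapped H3K27ac with their summit outside it had a median fold of 8.42, above the 7.15 of the 19492 with the summit inside. The 1950 TEAD regions that touched 2 or 3 H3K27ac regions had a median fold of 10.7. They were also wider, with a median of 611 bp against 463 bp for all TEAD regions. Their median fold was 10.7 for the 1500 with the summit outside H3K27ac and 10.8 for the 450 with the summit inside.

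The marked share did not rise steadily with TEAD fold. It was 75.7% (74.2 to 77.0%) in the decile of lowest fold, fell to 59.6% (58.0 to 61.3%) in the fourth decile and rose to 83.3% (82.0 to 84.5%) in the decile of highest fold. The median recovered background fell from 3.51 reads in the lowest decile to 2.21 in the fourth. From the fifth to the eighth decile it stayed between 2.19 and 2.26 while the marked share rose to 69.5%, and it was 2.45 in the highest. Across quintiles of recovered background the marked share was 41.3%, 61.4%, 76.2%, 78.0% and 85.1% from the lowest to the highest. Of the 100 TEAD regions of highest fold, 93 were marked.

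**Figure D1:**
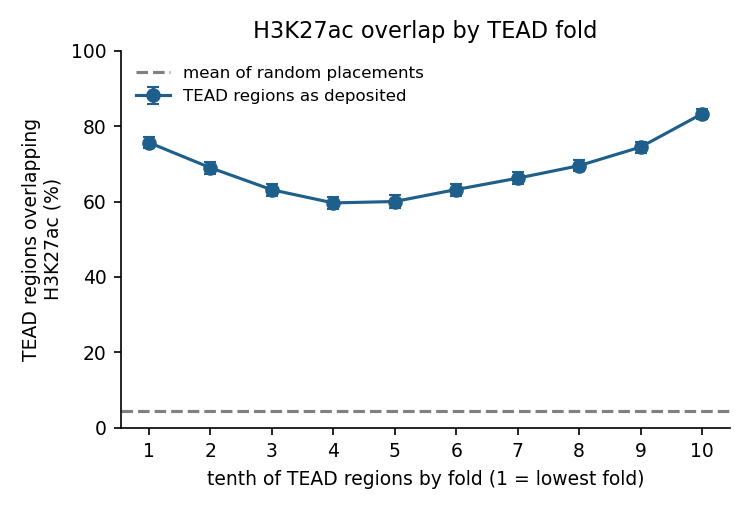
Share of TEAD regions that overlap an H3K27ac region (y axis, percent) in deciles of TEAD fold (x axis, lowest to highest); points are the shares, bars 95% Wilson intervals, and the dashed line the mean of random placements. The share is 75.7% in the lowest decile, 59.6% in the fourth and 83.3% in the highest, all above the placed 4.45%.

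The 10 strongest marked TEAD regions reached up to 145-fold, with summit pileups of 262 to 380 reads over a recovered background of 1.57 to 2.85. The strongest lay on chromosome 18 from 71983783 to 71984680, with 376 reads at the summit and a fold of 145 (counting interval 131 to 160), inside an H3K27ac region of 3038 bp at 19.3-fold. Another lay on chromosome 1 from 205270244 to 205271148 (110-fold, 99.5 to 122) within an H3K27ac region of 6317 bp that held 2 TEAD regions. A region on chromosome 3 from 66101257 to 66102092 reached 109-fold (96.4 to 122). Both chromosome 17 regions in this group, from 48105485 to 48106321 and from 43448801 to 43449825, sat in H3K27ac regions of 28.5- and 31.5-fold. The remaining 5 lay on chromosome 7 from 46184760, chromosome 10 from 21581393, chromosome 19 from 6578655, chromosome 11 from 843777 and chromosome 18 from 26745111. Apart from the strongest, the counting intervals of these regions overlapped one another, so their order is not resolved. H3K27ac fold under the 10 regions ran from 10.4 to 38.7.

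Strong TEAD regions also occurred without a called H3K27ac region. The 10 strongest unmarked regions ranged from 60.4- to 91.8-fold. The highest value lay on chromosome 10 from 46298649 to 46299658, with 210 reads at the summit and a fold of 91.8 (79.9 to 105). Others lay on chromosome 11 from 130642032 to 130643046 (78.3-fold), chromosome 19 from 10962582 to 10963374 (77.5-fold) and chromosome 2 from 12164174 to 12164944 (75.7-fold); the counting intervals of these regions overlapped. Among all 11132 unmarked TEAD regions, 29.9% (29.04 to 30.74%) lay within 5 kb of an H3K27ac region. Placements outside H3K27ac gave 13.5% ± 0.34 (SD), a ratio of 2.21 (permutation p = 0.002, the smallest possible). These placements were uniform along the chromosome, so clustering of both lists in the same stretches can also raise the ratio. In the overlap comparison, TEAD regions moved 5 to 50 kb reached 10.3%, against 4.45% for uniform placements. No such local move was run for nearness, so nearness beyond shared stretches was not tested.

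H3K27ac regions with TEAD were wider and stronger than those without. Their median width was 1647 bp against 659 bp and their median fold 9.63 against 5.31. The share with TEAD rose through the width deciles from 740 of the 5267 narrowest to 4643 of the 5267 widest (88.2%), and through the fold deciles from 16.9% to 72.1%. A wider region can hold a TEAD region by size alone, and these shares do not separate size from occupancy. Mean log2 H3K27ac fold was 3.27 ± 0.83 (SD) with TEAD and 2.62 ± 0.73 (SD) without, a difference of 0.65. Within width deciles the difference was 0.10 ± 0.01 (SE; permutation p = 1e-05, the smallest possible), and it was 0.05 when only TEAD regions of at least 5-fold were counted.

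TEAD summits inside H3K27ac were less frequent near the H3K27ac summit than uniform positions, and more frequent 300 to 450 bp from it. No other factor was profiled, so whether this offset is particular to TEAD was not tested. Among the 19492 TEAD summits inside H3K27ac, the median distance to the region's H3K27ac summit was 400 bp (interquartile range 252 to 692 bp). Within 150 bp lay 11.1% of TEAD summits, 0.69 times the share of uniform positions in the same regions (permutation p = 0.002, the smallest possible). Between 300 and 450 bp lay 23.5% against 11.5%, a ratio of 2.05. Beyond 1000 bp the ratio was 0.57. TEAD summits lay on the lower-coordinate side in 49.3% of cases. The depletion within 150 bp was also present in H3K27ac regions of at most 2000 bp that held 1 TEAD summit (20.8% against 28.2%).

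**Figure D2:**
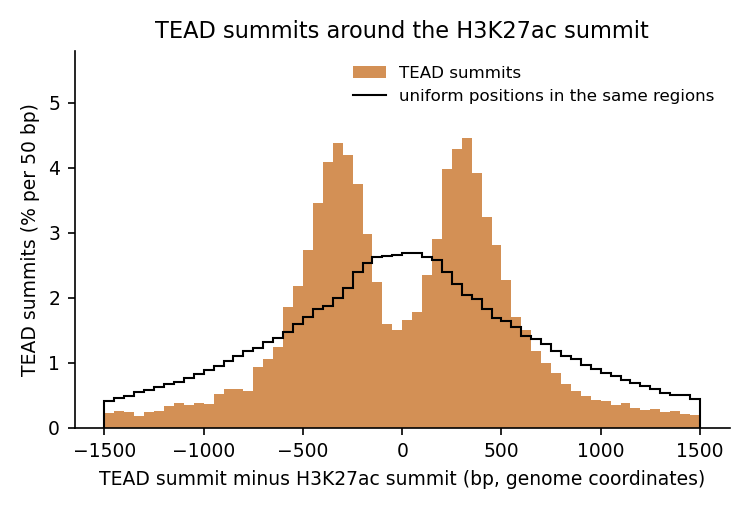
Position of the 19492 TEAD summits relative to the H3K27ac summit of the region they lie in (x axis, bp; y axis, percent of TEAD summits per 50 bp bin); the black line gives uniform positions in the same regions. TEAD summits form a peak on either side, with 23.5% of them 300 to 450 bp away, and a dip at the H3K27ac summit.

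The last comparison asked whether TEAD favoured the largest clusters of acetylation. Stitching gave 22587 H3K27ac domains, of which 863 were large, with a median span of 38.0 kb against 2.08 kb for the others. A TEAD region lay in 862 of the 863 large domains, with a median of 5 per domain, and in 58.4% of the others, which were far shorter. Per 10 kb of H3K27ac, large domains held 2.46 TEAD summits (95% counting interval 2.39 to 2.53) and the others 2.60 (2.56 to 2.65), with no matching on region width. The large domain without one lay on chromosome 1 from 54194934 to 54207392 and was looked up after the count had been seen. Large domains held 5173 TEAD regions, 14.7% of all. Member H3K27ac regions of large domains carried TEAD in 41.0% of cases and those elsewhere in 41.8%. The unmatched shares ran the other way with a 5 kb stitching gap (43.9% against 41.4%), with TEAD regions of at least 5 in −log10 q (39.4% against 38.8%) and of at least 5-fold (35.4% against 34.6%). At equal width the share was lower in large domains, with a ratio of 0.80 (95% interval 0.78 to 0.82; permutation p = 0.0002, the smallest possible). Without matching on width the ratio was 0.98 and did not pass the test (permutation p = 0.14). Both tests took single H3K27ac regions as units, 8427 of them in the 863 large domains. Members of a domain are not independent, so the interval may be too narrow and the p-values too small.

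The highest-ranked domain spanned chromosome 14 from 61927711 to 62089925 (162 kb) with 29 H3K27ac regions and 37 TEAD regions, the strongest of them 40.5-fold. The second, on chromosome 6 from 43945355 to 44047497, held 18 TEAD regions, and the third, on chromosome 1 from 8064857 to 8280256, held 37 among 56 H3K27ac regions. The fourth, on chromosome 7 from 27134998 to 27224669, held 25 TEAD regions. A second chromosome 6 domain, from 45575300 to 45685030, held 14 TEAD regions. The domain on chromosome 9 from 114754068 to 114839498 held 15 TEAD regions, the strongest at 67.8-fold, and that on chromosome 5 from 149828167 to 149904294 held 14, the strongest at 65.4-fold. The remaining domains among the highest 10 lay on chromosome 10 from 74019559 to 74100267, chromosome 22 from 46430986 to 46513040 and chromosome 9 from 132220801 to 132269878. The last of these held 9 TEAD regions, none above 11.6-fold, under an H3K27ac summit of 48.6-fold.

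**Figure D3:**
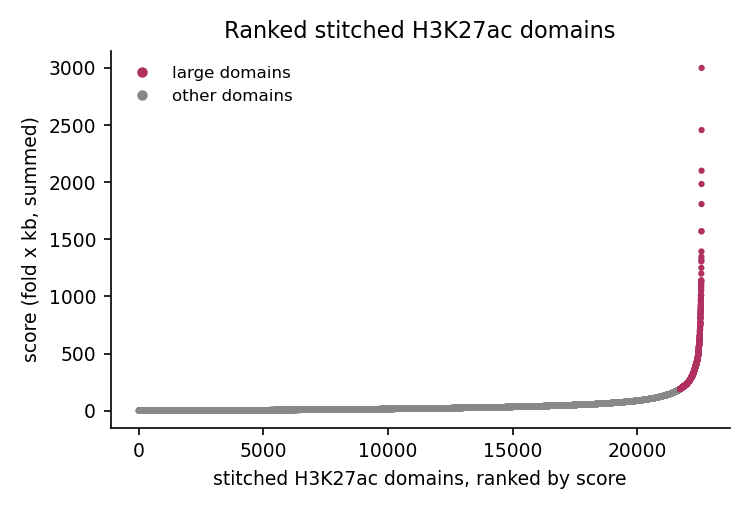
Stitched H3K27ac domains ranked by the sum of fold times width (x axis, rank from the lowest; y axis, score in fold times kb), with the 863 large domains coloured. The curve bends sharply at its right end, where the large domains lie.

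Region density and background differed between chromosomes. Chromosome X had the fewest TEAD regions per Mb of placeable sequence, 7.93, and chromosome 22 the most, 23.4. Placeable sequence leaves out stretches of over 1 Mb without a peak, so these densities depend on the lists themselves. DNA copy number was not measured, so a chromosome's density is not separated from its number of copies. H3K27ac density ran from 14.2 per Mb on chromosome 13 to 36.7 on chromosome 22. The number of TEAD regions per H3K27ac region was lowest on chromosome X (0.527) and highest on chromosome 7 (0.750). The marked share of TEAD regions ran from 59.3% (54.9 to 63.5%) on chromosome 13 to 75.4% (72.2 to 78.3%) on chromosome 22. Mean recovered background at H3K27ac regions was 1.86 reads on chromosome 13, 1.95 on chromosome X and 3.67 on chromosome 7. The floor of the background held 47.6% of these regions on chromosome 13, 44.1% on X and 0.29% on 7, which limits how low the means can go. Without chromosomes 13 and X, the marked share was 39.2% in the lowest and 85.2% in the highest quintile of background.

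**Figure D4:**
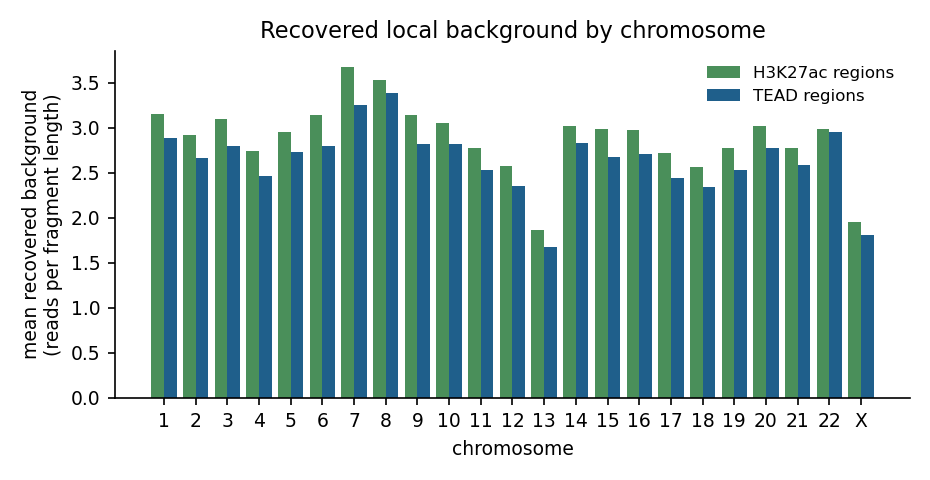
Mean recovered local background (y axis, reads per fragment length) at H3K27ac and TEAD regions of each chromosome (x axis). Chromosomes 13 and X have the lowest bars (1.86 and 1.95 at H3K27ac regions) and, at H3K27ac regions, chromosome 7 has the highest (3.67); at TEAD regions chromosome 8 has the highest (3.38).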

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

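All tests in this part were chosen after the pattern they concern had been seen; for the release of input fragments the values bearing on the test had been seen as well.

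The recovered background was not part of any planned comparison. It exceeded 10 reads at 32 TEAD regions, of which 16 were marked, with a median fold of 3.30. The highest values were 143 reads on chromosome 22 from 18717963 to 18718234 (2.05-fold) and 50.5 reads on chromosome 20 from 26189781 to 26190318 (3.38-fold). Others lay near chromosome ends, on chromosome 1 from 10030 to 10327 (27.4 reads) and chromosome X from 155260059 to 155260403 (41.4 reads). Without these 32 regions the overlap ratio was 15.4. They were too few among 35241 TEAD regions to change it, so the check carries little weight.

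Mean recovered background at H3K27ac regions was 3.53 reads on chromosome 8 and 1.86 on chromosome 13, a ratio of 1.89. Of these regions 15.1% on chromosome 8 and 47.6% on chromosome 13 sat at the floor of 1.45 reads. The floor bounds the means from below, so the ratio is not a ratio of control signal. Wider H3K27ac regions on chromosome 8 are argued against, since the ratio stayed above 1.2 in 10 of 10 width deciles, between 1.69 and 2.13; strata of H3K27ac fold were not run. Unequal DNA copy number in this line is a candidate explanation and stays open. Adjacent 5 Mb bins had correlated background after the chromosome mean was removed, with Pearson r = 0.73 across 485 pairs of bins. The one-sided permutation p was 0.001, the smallest possible, and bins are not independent replicates. However, chromatin domains of that size would give the same correlation. No explanation beyond region width and DNA copy number was tested, as the design names none.

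The marked share of TEAD regions was 43.9 percentage points higher in the highest than in the lowest quintile of background. Within deciles of the mean background of the 5 Mb bin the difference was 51.5 points (95% interval 49.9 to 53.1). That argues against copy number changes as broad as the bins as the cause. The bin mean only stands in for copy number, which was not measured, and smaller changes stay open. Acetylated chromatin that releases input fragments more easily may raise the background there: it was 1.41 times higher in the widest than in the narrowest decile of H3K27ac regions (95% interval 1.39 to 1.43). Since weak, narrow regions pass the caller more easily where background is low, these cannot be told apart without the input reads.

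The marked share was 15.6 percentage points higher in the lowest decile of TEAD fold than in the fifth. Stratified on quintiles of background the difference was 3.45 points (95% interval 1.16 to 5.74), but this pools opposite signs: the lowest decile was higher by 5.33 to 8.87 points in the 4 lower quintiles (in 1 of them the 95% interval included 0) and lower, 80.7% against 86.5%, in the highest. High background at the weakest peaks may account for part of the difference and stays open. The weakest marked TEAD regions lay on stronger H3K27ac than those of the fifth decile, by 0.22 in mean log2 fold (95% interval 0.17 to 0.26). That is consistent with signal that open or acetylated chromatin gives in any ChIP, a reading that an unrelated antibody would be needed to separate from weak TEAD binding.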

How the results depend on the processing

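Of 29 alternatives, 28 kept the direction and the side of the threshold. Of the 29, 12 were planned and 17 chosen after the data had been seen, among them all those for H3K27ac regions with TEAD, summit distance and unmarked TEAD regions near H3K27ac. The exception was the lower share of H3K27ac regions with TEAD in large domains, where the ratio of 0.80 became 0.98 (permutation p = 0.14) without matching on width, since member regions differ in width; the other 4 alternatives gave at most 0.82. The overlap ratio of TEAD with H3K27ac ran from 6.62, for TEAD regions moved 5 to 50 kb, to 18.8, with no stretch excluded from placement. Stricter thresholds gave overlap shares of 61.3 to 68.3%. The log2 fold difference between marked and unmarked TEAD regions ran from 0.04 to 0.27. The alternative on log2 summit pileup, which is not a fold, gave 0.46. The log2 fold difference between H3K27ac regions with and without TEAD ran from 0.05 to 0.65. The summit depletion ratio ran from 0.61 to 0.74, and the excess of unmarked TEAD regions near H3K27ac from 1.57 to 2.13. Promoter shares, motif shares, their co-occurrence, gene lists and the alternatives that set promoters apart were not run, because hg19 sequence and gene positions were not used here. No replicate could be left out, as each group had 1 library. Depth limits the unmarked class: a summit with fewer than 7 reads was never called in the H3K27ac list.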

Other observations

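Several H3K27ac regions carried many TEAD regions. The most were 16, in the widest H3K27ac region of the list, on chromosome 14 from 62012651 to 62058208 (45.6 kb, 33.4-fold), inside the highest-ranked domain. The second, on chromosome 1 from 43393425 to 43430603 (37.2 kb), carried 11, and the third, on chromosome 7 from 27148143 to 27172289 (24.1 kb), carried 9. Regions on chromosome 17 from 48120747 to 48144838, chromosome 2 from 206555809 to 206574451, chromosome 11 from 118779295 to 118797179 and chromosome 10 from 95218771 to 95235858 carried 8 each.

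Among TEAD regions that overlapped exactly 1 H3K27ac region, the 3117 with the summit outside it had a median fold of 7.62 (interquartile range 5.52 to 12.2) and the 19042 with the summit inside 7.10 (5.20 to 11.8). Median widths were 472 and 504 bp. The difference was not tested.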
